A study of Caenorhabditis elegans with 27 samples.

How the data were processed

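Poly(A) RNA from whole Caenorhabditis elegans was sequenced as stranded libraries (dUTP method, per the labels' protocols) in 4 strains that express the plant F-box protein TIR1. Auxin (1 mM indole-3-acetic acid) lets TIR1 send degron-tagged proteins to the proteasome. CA1200 carries no tagged target and was the control. In AM05 topoisomerase I (TOP-1) carries the degron, in SS01A topoisomerase II (TOP-2), and in AM01 DPY-27, the condensin DC subunit that binds the X chromosomes in dosage compensation. These are called the TOP-1, TOP-2 and DPY-27 strains. Worms were sampled without auxin and after 30, 60 and 120 min of auxin, in the DPY-27 strain only without auxin and after 120 min. Each of the 14 groups had 2 libraries, except CA1200 at 60 min with 1, so 27 libraries were used. Worms were at larval stages L2/L3, except 2 mixed-stage libraries of the DPY-27 strain, 1 per time point, called its replicate 2 here. The time at which the no-auxin aliquots were collected is not stated.

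The deposited files for single libraries give each gene's FPKM and TPM, per the file headers, computed by the authors with Cufflinks. TPM was used for all tests here. FPKM was used only to estimate depth: in genes with few reads, FPKM times gene length rises in steps of 1 fragment, and 1 step gives the number of fragments behind the library. This gave 5.74 to 21.4 M fragments per library. The deposited comparison tables give a mean signal over samples (baseMean), a log2 fold change, a test score (stat), a p-value and an adjusted p-value per gene, made by the authors with DESeq2. Those 16 tables cover the 2 topoisomerase strains over time and all 3 degron strains against CA1200, and are quoted only where named as the authors' deposited table. The submitters' processing notes name CASAVA 1.8, HISAT2 2.2.1, HTSeq 0.13.5, Cufflinks 2.2.1 and DESeq2 1.30.0 as the authors' tools. HTSeq counts per library were not used here.

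Each library file held 20390 genes. Symbols were matched by sequence name to the reference annotation, which gave 19900 matches. 2 sequence names stood on more than 1 line and were kept apart. Coordinates are those of the files; their genome build is not given in the sources used here, and only 1.37% of matched genes start at the same base in the reference. Between 1 and 16 genes per library carried a FAIL status, and their values were used as listed. Genes of the mitochondrial genome were listed at exactly 0 in every library and were not tested. TPM was scaled between libraries by median ratios over the 12647 genes used for that step, and log2(scaled TPM + 1) was taken. Fold changes on this scale understate the ratio in genes with low TPM. Genes with a TPM of at least 1 in at least 2 libraries were tested, 14271 in number, of which 2227 are X-linked and 12044 autosomal.

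limma 3.58.1 (R 4.3.3) fitted a mean for each strain and time plus a term for the mixed-stage libraries, over all 27 libraries, with moderated variances that follow the mean level. The fit had 12 residual degrees of freedom. The mixed-stage term takes up the level of DPY-27 replicate 2, so differences between the DPY-27 strain and CA1200 rest on the level of replicate 1, while the 120 min change uses both replicates. A lone library at CA1200 60 min is thereby assumed to vary like the other groups. Comparisons were auxin against no auxin within each strain, each degron strain against CA1200 at the same time, the difference between strains in the 120 min change, and the same difference between the TOP-1 and TOP-2 strains. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. All limma p-values are two-sided. X-linked against autosomal genes, the longest 10% of genes by genomic span (1428 genes of at least 7742 bp) against the others, and 27 gene lists fixed before the data were examined were tested with camera in limma, with a preset correlation between genes of 0.01. The alternative estimated that correlation from the residuals. P-values were adjusted over 14 comparisons for the X chromosome, 6 for gene span and 27 lists within each of 11 comparisons. Exact permutation tests exchanged auxin and no-auxin labels within replicates. Effects on X-linked or long genes are differences of medians.

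The gene lists were degron targets, condensin subunits, dosage compensation recruiters, cohesin and DNA topology, DNA damage and repair, replication and cell cycle, histones, cytosolic heat shock, unfolded protein response of endoplasmic reticulum and mitochondria, intracellular pathogen response, innate immunity, xenobiotic detoxification, cuticle collagens, molting cycle, neurons, body wall muscle, intestine, pharynx, hypodermis and seam, germline, oocyte and embryo, sperm, ribosomal proteins, nuclear-encoded oxidative phosphorylation, starvation and insulin/FOXO targets, stress-induced transcription factors, and RNA polymerase II transcription. A further list, yolk proteins and adult hypodermis, had 1 tested member, col-62, so only that gene is given.

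Genes were named by a rule. The 3 targets top-1, top-2 and dpy-27 are always named. Otherwise the genes with the largest changes were named, 10 in each direction for the 120 min comparison within a degron strain, 5 for CA1200 at 120 min, for strain differences without auxin and for differences between changes, and 3 for the rest. They had an adjusted p under 0.05, a mean TPM of at least 5 over the libraries compared and every library of one group above the other. Up to 4 members of each list with the largest moderated statistics could also be named. Where fewer genes passed, fewer are named, and exceptions are stated beside the gene. A gene without a symbol keeps its sequence name.

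In CA1200 and the topoisomerase strains the labels number the replicates 1 and 2 (only 1 in CA1200 at 60 min). In the DPY-27 strain they give all 4 libraries the number 1, and its libraries were paired by stage. Same-numbered libraries deviated together: the correlations of their deviations from the group means ran from 0.377 to 0.697 in CA1200, 0.627 to 0.903 in the TOP-1 strain and 0.785 to 0.886 in the TOP-2 strain. Libraries of the same stage in the DPY-27 strain stood at 0.801, and between strains the correlations ran from -0.305 to 0.0602. The number was therefore taken to pair libraries within CA1200 and the topoisomerase strains. A fit with the replicate number as a block within CA1200 and the 2 topoisomerase strains, with 9 residual degrees of freedom, was an alternative, and its values stand beside results whose call it changes. In comparisons between strains, the block removes variation between replicates that the strain difference has to be measured against, so its counts there are upper values.

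Other alternatives were a pseudocount of 0.1, no filter, TPM as deposited without scaling, only the groups compared in the fit, and each library left out in turn. An alternative chosen after seeing the data left out 6 libraries that stand apart from the others. The replicate block was not planned for the gene lists. Scaling was compared with TPM as deposited: without it, the median of all genes moved by -0.22 in the TOP-2 strain at 30 min, by -0.11 for the TOP-1 change minus CA1200, and by 0.18 for the TOP-1 strain against CA1200 at 60 min. Against CA1200 it moved by 0.45, 0.25, 0.48 and 0.37 for the TOP-2 strain from 0 to 120 min, and by 0.84 and 0.81 for the DPY-27 strain at 0 and 120 min.

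The scripts were tested on simulated data for the 120 min comparison in the TOP-1 strain, with 200 of 14271 genes changed in each of 10 simulations. Means, replicate differences and noise were drawn from the fit with the block, with noise independent between genes. The main fit recovered 2.39%, 44.6% and 66.4% of genes changed by 1, 2 and 3 on the log2 scale, with 0.265% false calls among its calls. With the block the shares were 52.4%, 87.0% and 89.1%, with 5.47% false calls. The advantage of the block was thus built into the simulation. A shift of 0.2 added to X-linked genes was returned as 0.202 and called in 20 of 20 simulations, against 0 of 20 with none added. Without correlation between genes in the noise, this does not test the rate of false calls for sets. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading files and drawing.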

Results

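Transcript levels were measured in whole worms of 4 strains by poly(A) RNA sequencing. CA1200, with no tagged target, the TOP-1 strain and the TOP-2 strain were each sampled at 0, 30, 60 and 120 min of auxin, and the DPY-27 strain at 0 and 120 min. Each group had 2 libraries except CA1200 at 60 min, which had 1. Estimated depth was 5.74 to 21.4 M fragments per library. Replicate 1 of the TOP-2 strain (4 libraries) and of the DPY-27 strain (2 libraries) stood apart from the other 21 libraries. Those 6 libraries had 5.74 to 9.45 M fragments against 11.6 to 21.4 M, a median TPM of 5.10 to 6.83 against 1.27 to 2.53, and 13146 to 13458 genes at a TPM of 1 or more against 10648 to 12024. Ribosomal protein genes took 17.2% to 25.7% of their TPM, against 31.9% to 38.9% in the other libraries. Levels below are scaled TPM as mean ± SD, and log2 fold changes are given ± their standard error from the limma fit.

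The degron acts on the protein, so transcript levels of the targets do not measure depletion. In the TOP-1 strain, top-1 stood at 35.7 ± 9.43 (SD, n = 2) without auxin, 29.4 ± 2.00 after 30 min, 24.7 ± 2.74 after 60 min and 25.7 ± 4.91 after 120 min. In CA1200 it stood at 38.8 ± 6.71, 33.6 ± 6.84, 25.5 (n = 1) and 31.7 ± 4.74. In the TOP-2 strain it stood at 49.8 ± 22.7, 49.1 ± 21.9, 47.8 ± 34.2 and 43.8 ± 26.1, and in the DPY-27 strain at 34.4 ± 13.03 and 41.05 ± 21.2. The transcript of top-2 in the TOP-2 strain was 7.89 ± 2.66, 8.10 ± 2.25, 7.36 ± 1.66 and 6.85 ± 0.303 over time. It was 14.1 ± 4.34, 10.5 ± 3.98, 6.71 and 10.9 ± 2.56 in CA1200, 20.5 ± 0.137, 15.9 ± 2.06, 16.38 ± 0.544 and 17.6 ± 1.02 in the TOP-1 strain, and 18.1 ± 3.96 and 13.8 ± 1.01 in the DPY-27 strain. Without auxin the top-2 difference between the TOP-2 strain and CA1200 was -0.77, with an adjusted p of 0.75, or 0.011 with the replicate block.

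The transcript of dpy-27 was 12.8 ± 1.77 (SD, n = 2) without auxin and 12.99 ± 0.0411 after 120 min in the DPY-27 strain, a log2 change of 0.02. It was 13.7 ± 4.78, 13.7 ± 6.54, 8.95 and 10.8 ± 4.19 over time in CA1200, and 13.1 ± 1.13, 16.397 ± 0.197, 12.1 ± 2.43 and 11.2 ± 1.83 in the TOP-2 strain. In the TOP-1 strain it was 17.7 ± 1.15, 16.6 ± 2.01, 15.2 ± 1.504 and 11.6 ± 1.86, and its 120 min change of -0.57 had an adjusted p of 0.505, or 0.0325 with the block. Over 120 min top-1 changed by -0.44 in the TOP-1 strain (adjusted p = 0.839, or 0.0755 with the block) and top-2 by -0.15 in the TOP-2 strain. The 3 targets as a list had a median of -0.44 in the TOP-1 strain, with an adjusted p of 0.395.

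The first question was what follows the degradation of topoisomerase I, which relaxes supercoils at transcribed genes. After 120 min of auxin, 118 genes were higher and 159 lower in the TOP-1 strain. Of the lower genes 94 were among the longest 10%, against 1 of the higher genes, and 31 higher and 4 lower genes were X-linked. Among genes called without the block, the largest rise was in F46C5.1 (chromosome II, 8820108 to 8821143), by 5.31 ± 0.94, from 6.07 ± 3.38 (SD, n = 2) to 269 ± 78.8 (adjusted p = 0.013). C50F7.5 (IV, 7726706 to 7727939) rose by 4.02 ± 0.95, from 70.6 ± 53.1 to 1020 ± 362. The alcohol dehydrogenase gene adh-1 (V, 11888216 to 11889631) rose by 3.48 ± 0.80, from 85.2 ± 22.8 to 974 ± 329. The lysozyme gene ilys-2 (IV, 2467679 to 2468878) rose by 3.56 ± 0.86, with 20.3 ± 23 after auxin. On the X chromosome, B0563.9 rose by 4.75 ± 1.09, M02D8.6 by 3.47 ± 0.65 and K01A12.4 by 3.32 ± 0.80. On the autosomes bigr-1 rose by 3.45 ± 0.67 and Y46C8AL.11 by 3.30 ± 0.70. F35F10.14 (V, 3319471 to 3319672) was listed at 0 in both libraries without auxin and stood at 17.6 ± 7.86 after 120 min (adjusted p = 0.00999).

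Among genes called without the block, the largest fall in the TOP-1 strain at 120 min was in R09E10.13 (IV, 10294814 to 10295245), by -5.74 ± 0.96, from 102 ± 30.8 (SD, n = 2) to 0.895 ± 0.34 (adjusted p = 0.00999). The co-chaperone gene dnj-13 (II, 11545636 to 11547302) fell from 517 ± 198 to 15.8 ± 1.63, a change of -4.89 ± 1.16. In CA1200 dnj-13 fell too, from 233 to 21.4 in replicate 1 and from 422 to 20.6 in replicate 2. In the TOP-1 strain the nuclear hormone receptor gene nhr-17 (X, 12663723 to 12667782) fell from 91.4 ± 26 to 7.31 ± 2.39, a change of -3.48 ± 0.74. The gene rhy-1, a regulator of the hypoxia factor HIF-1, fell from 33.3 ± 2.07 to 5.11 ± 1.26, a change of -2.50 ± 0.48. In CA1200 rhy-1 went from 21.6 to 13.9 in replicate 1 and from 17.9 to 7.67 in replicate 2. Falls in the TOP-1 strain in taco-1 (-2.46 ± 0.43), F26A3.4 (-2.46 ± 0.34), F54A3.2 (-2.45 ± 0.51), Y50D7A.3 (-2.34 ± 0.29), the dicarboxylate transporter gene nac-3 (-2.29 ± 0.44) and Y48E1B.3 (-2.28 ± 0.31) completed the named genes. Y48E1B.3 spans 20752 bp and fell from 19.1 ± 0.614 to 3.15 ± 0.0352.

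With the replicate block, 1642 genes were higher and 1638 lower at 120 min in the TOP-1 strain, and all 277 genes of the main fit were among them. Genes called with the block alone, chosen after their values were seen, included the inducible chaperone gene hsp-70 at -6.82, which went from 250 ± 32.6 (SD, n = 2) to 1.21 ± 0.108 (adjusted p = 0.166, or 2.08e-04 with the block). They also included the metallothionein gene mtl-1 at 4.59, which went from 12.4 ± 2.45 to 320 ± 8.62 (adjusted p = 0.175, or 4.36e-04 with the block), and far-3 at 3.54. The near-identical pair F44E5.4 and F44E5.5, both at -8.24, and hsp-16.2 at -5.69 share reads with close copies, so the value of each single gene is uncertain. With TPM as deposited, 2 genes were higher and 7 lower, against 118 and 159 here. The count of 277 became 19 without the no-auxin replicate 1 library, 18 without no-auxin replicate 2, 16 without 120 min replicate 1 and 109 without 120 min replicate 2. The authors' deposited table for this comparison calls 196 genes higher and 284 lower, of which 28 and 11 are X-linked, and its 284 lower genes include 136 of the longest.

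Among the gene lists, the 12 cytosolic heat shock genes all had negative changes in the TOP-1 strain at 120 min, with a median of -4.82 (adjusted p = 1.27e-07, but adjusted p = 0.539 with an estimated correlation). Of them 1, dnj-13, fell over all genes tested, 7 when adjusted over the list alone and 10 with the block, and hsp-110 had -4.75 (adjusted p = 0.143, or 7.53e-04 with the block). Of 16 unfolded protein response genes 13 were negative, with a median of -0.65 (adjusted p = 2.13e-04, but adjusted p = 0.297 with an estimated correlation). The endoplasmic reticulum stress kinase gene pek-1 fell by -1.51 (adjusted p = 0.0242), 3 genes fell when adjusted over the list alone and 7 with the block. The chaperone gene hsp-4 had -3.97 (adjusted p = 0.0593, or 1.53e-04 with the block). Of 209 xenobiotic detoxification genes 166 were positive, with a median of 0.51 (adjusted p = 2.07e-07, but adjusted p = 0.539 with an estimated correlation). The glucuronosyltransferase genes ugt-37, by 1.58, and ugt-14, by 2.75, rose both over all genes and over the list alone, and 63 were higher and 6 lower with the block.

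Of 36 molting cycle genes 30 were negative in the TOP-1 strain at 120 min, with a median of -0.91 (adjusted p = 0.0103, but adjusted p = 0.998 with an estimated correlation). None of them passed over all genes or over the list alone, and 2 were higher and 18 lower with the block. Values were -3.55 for mlt-11 (adjusted p = 8.74e-05 with the block), -2.80 for ptr-18, -2.28 for fbn-1 and -0.84 for bli-4. Of the 36 molting genes 8 were among the longest 10%, so this list overlaps with the long-gene change. Of 26 genes of RNA polymerase II transcription 18 were negative, with a median of -0.24 (adjusted p = 0.0129, but adjusted p = 0.539 with an estimated correlation). The elongation kinase gene cdk-9 fell by -1.07 (adjusted p = 0.0335), 2 genes fell when adjusted over the list alone, and taf-1, of the general factor TFIID, had -1.52 (adjusted p = 0.0929). The intracellular pathogen response list (41 genes, median 0.27) and the body wall muscle list (26 genes, median -0.20) had an adjusted p of 0.131 and 0.0763, both 0.029 with the block and 0.894 with the block and an estimated correlation. Of the 26 muscle genes 10 were among the longest 10%.

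The other lists had no call as a group in the TOP-1 strain at 120 min. Their medians were -0.13 for 9 condensin subunits, 0.08 for 8 dosage compensation recruiters, -0.21 for cohesin and DNA topology, 0.07 for DNA damage and repair, -0.12 for replication and cell cycle and 0.38 for histones. They were 0.11 for innate immunity, 0.001 for cuticle collagens, -0.09 for neurons, -0.04 for the intestine, -0.42 for the pharynx, 0.18 for hypodermis and seam, 0.04 for the germline, 0.08 for oocyte and embryo and -0.38 for sperm. They were 0.20 for ribosomal proteins, 0.16 for oxidative phosphorylation, 0.24 for starvation and insulin/FOXO targets and -0.25 for stress-induced transcription factors. Single members of these lists that passed included the lysozyme gene lys-3, which rose by 1.75 (adjusted p = 0.0462), the X-linked collagen gene col-181, by 1.099 (adjusted p = 0.0373), and the cytochrome oxidase assembly gene cox-18, which fell by -1.61 (adjusted p = 0.0439). The adult marker col-62 had 0.46 (adjusted p = 0.785). Of the genes that bring condensin DC to the X or act with it, dpy-21 had -1.69 (adjusted p = 0.143, or 7.64e-04 with the block) and dpy-28 had -1.08 (0.00533 with the block).

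The 30 and 60 min samples show how early these changes begin. After 30 min in the TOP-1 strain the only gene called, which fell, was rhy-1, from 33.3 ± 2.07 (SD, n = 2) to 1.58 ± 0.772, a change of -3.76 ± 0.48 (adjusted p = 0.0163). In CA1200 rhy-1 fell at 30 min too, from 21.6 to 2.58 and from 17.9 to 2.68 in replicates 1 and 2. In the TOP-1 strain 918 genes had an unadjusted p under 0.05 in limma at 30 min, 249 were higher and 449 lower with the block, and the authors' deposited table calls 29 higher and 40 lower. With the block, mtl-1 at 3.08, the cytochrome P450 gene cyp-35C1 at 3.04 and W08A12.2 at 2.37 were higher, and R107.5 at -5.04 and Y43F8B.2 at -3.51 lower. Of these, mtl-1 (118 to 839 and 15.4 to 114) and cyp-35C1 (2.59 to 99.1 and 1.99 to 37.7) also rose in CA1200 at 30 min. After 60 min in the TOP-1 strain, 19 genes were higher and 55 lower, 32 of the lower among the longest 10%. The acyltransferase gene oac-6 (V, 16302727 to 16306136) rose by 2.95 ± 0.42, ugt-41 by 2.71 ± 0.56 and nhr-202 by 2.12 ± 0.40. Falls were seen in rhy-1 (-3.69 ± 0.48), F26A3.4 (-2.56 ± 0.34) and usp-39 (-2.08 ± 0.29). The block gave 944 higher and 1146 lower at 60 min, and the authors' deposited table calls 115 higher and 205 lower. The call of rhy-1 at 30 min was lost without any single one of the 4 libraries (no-auxin and 30 min, replicates 1 and 2). The 60 min count of 74 became 0 without no-auxin replicate 1, 1 without no-auxin replicate 2, 3 without 60 min replicate 1 and 0 without 60 min replicate 2.

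The second question was whether X-linked genes, on which condensin DC acts, respond apart from autosomal genes. After 120 min, X-linked genes were higher relative to autosomal genes by 0.21 in the TOP-1 strain (0.191 and 0.231 in replicates 1 and 2, adjusted p = 4.45e-05), 0.24 in the TOP-2 strain (0.226 and 0.220, adjusted p = 4.89e-12) and 0.15 in the DPY-27 strain (0.128 and 0.158, adjusted p = 4.38e-06). In CA1200 the value was 0.02 (0 and 0.0543, adjusted p = 0.584). The difference from CA1200 was 0.19 for the TOP-1 strain (adjusted p = 1.78e-05), 0.22 for the TOP-2 strain (1.03e-06) and 0.12 for the DPY-27 strain (0.0025), and the TOP-1 and TOP-2 strains differed by -0.003. All these calls held with an estimated correlation. The TOP-1 difference from CA1200 was 0.117 without TOP-1 no-auxin replicate 2. The DPY-27 difference was 0.104 and no longer passed without DPY-27 replicate 2, at 0 or at 120 min. Median changes of single autosomes at 120 min were -0.08 to 0.16 in the TOP-1 strain, with 0.16 on chromosome V, -0.06 to 0.01 in the TOP-2 strain and -0.04 to 0.00 in the DPY-27 strain.

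Over time in the TOP-1 strain the X minus autosome value was 0.10 at 30 min (adjusted p = 6.19e-04) and 0.18 at 60 min (2.16e-05). In the TOP-2 strain it was -0.004 at 30 min (adjusted p = 0.904) and 0.12 at 60 min (7.69e-05). The TOP-1 value at 30 min was 0.0399 and lost its call without no-auxin replicate 2, 0.189 without no-auxin replicate 1 and 0.167 without 30 min replicate 2. Its value at 60 min was 0.115 without no-auxin replicate 2 and 0.277 without no-auxin replicate 1. At 30 min the TOP-2 value turned to 0.026 without no-auxin replicate 2. The TOP-2 value at 60 min lost its call without no-auxin replicate 1 (0.0947) and without 60 min replicate 2 (0.0901), and was 0.198 without 60 min replicate 1. An exact permutation test over 16 arrangements gave a two-sided p of 0.0625 for the TOP-1 strain, the smallest possible, and 0.375 for the TOP-2 strain. In CA1200 the exact test over 12 arrangements gave 0.75, where the smallest possible was 0.0833.

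**Figure D1:**
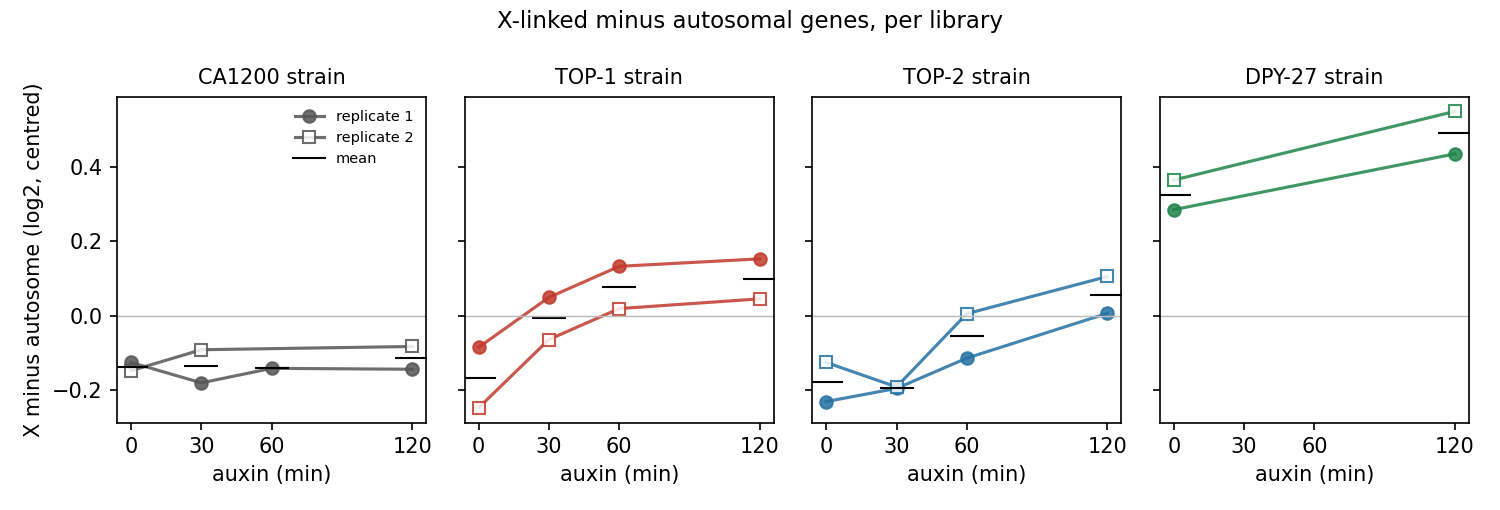
Median of X-linked minus median of autosomal genes (log2, each gene centred on its mean over 27 libraries, vertical axis) against minutes of auxin, 1 panel per strain; filled circles are replicate 1, open squares replicate 2 and dashes their mean. As medians of fitted fold changes, which are not the values plotted, X-linked genes rose relative to autosomes over 120 min by 0.21, 0.24 and 0.15 in the TOP-1, TOP-2 and DPY-27 strains. The same change was 0.02 in CA1200.

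Gene span separated the strains differently. In the TOP-1 strain at 120 min the longest 10% of genes were lower than other genes by -0.50 (replicates -0.550 and -0.464, adjusted p = 1.77e-22, but adjusted p = 0.0723 with an estimated correlation). The same difference was -0.18 in the TOP-2 strain (replicates -0.232 and -0.121, adjusted p = 1.95e-09, but adjusted p = 0.272 with an estimated correlation). It was -0.04 in CA1200 (adjusted p = 0.316) and 0.01 in the DPY-27 strain (adjusted p = 0.788). Against CA1200 the TOP-1 strain had -0.48 (adjusted p = 1.79e-28, but adjusted p = 0.0723 with an estimated correlation) and the TOP-2 strain -0.14 (adjusted p = 1.94e-04, but adjusted p = 0.506 with an estimated correlation). Median changes in the TOP-1 strain went from 0.22 in the shortest 10% to -0.16 and -0.41 in the longest 2 of the 10 classes.

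Earlier in the TOP-1 strain the long-gene difference was -0.42 at 30 min and -0.47 at 60 min, given as values. CA1200 had -0.17 at 30 min, with replicates at -0.379 and 0.0231, and -0.33 at 60 min. In CA1200 at 120 min the value was -0.151 without no-auxin replicate 1 (adjusted p = 5.98e-04) and -0.206 without 120 min replicate 2 (4.90e-07), which then passed. It also passed in the other direction, at 0.136 without 120 min replicate 1 (adjusted p = 0.00108), and was 0.0712 without no-auxin replicate 2 (adjusted p = 0.0651). The TOP-2 difference from CA1200 turned to 0.03 without CA1200 120 min replicate 2. It was -0.0424 without CA1200 no-auxin replicate 1, -0.0445 without TOP-2 120 min replicate 1 and -0.0944 without TOP-2 no-auxin replicate 2, all short of a call. It was -0.263 without CA1200 no-auxin replicate 2, -0.314 without CA1200 120 min replicate 1 and -0.209 without TOP-2 120 min replicate 2. The TOP-1 difference from CA1200 was -0.303 without CA1200 120 min replicate 2, and the change within the TOP-2 strain -0.0921 without its 120 min replicate 1. The exact permutation test, two-sided and with all auxin times pooled, gave 0.0625 for the TOP-1 strain, 0.188 for the TOP-2 strain and 0.5 for CA1200. It does not test the 120 min change alone.

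**Figure D2:**
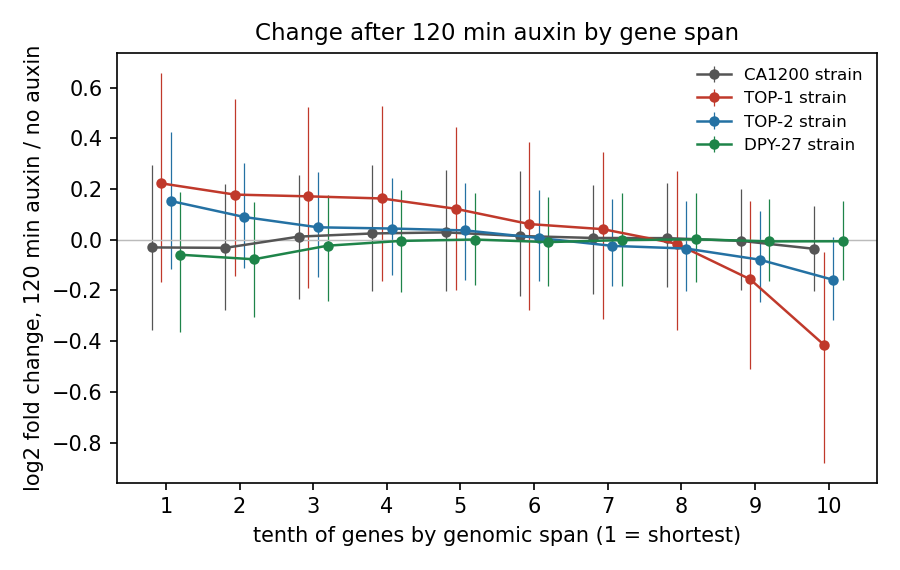
Median log2 fold change after 120 min of auxin (vertical axis) in 10 classes of genes by genomic span, from shortest to longest (horizontal axis), in 4 strains; bars run from the 25th to the 75th percentile of genes. The longest class stands at -0.41 in the TOP-1 strain, with bars from -0.88 to -0.05.

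Degradation of topoisomerase II, which untangles and decatenates DNA, was followed in the same way. In the TOP-2 strain 0 genes passed in limma at 30, 60 or 120 min, with 205, 187 and 235 at an unadjusted p under 0.05. With 14271 genes tested, that threshold gives more genes than this without any change. The spread of the main fit includes variation between replicates, so its 0 calls do not show that few genes changed. With the block 1596, 1453 and 1438 genes had an unadjusted p under 0.05. The authors' deposited tables call 1, 0 and 0 genes. With the block 3 genes were higher at 30 min, all chosen after their values were seen, F59C12.4 (X, 16602371 to 16602644) at 2.59, T07D1.3 (X, 2442776 to 2443396) at 1.31 and ZK1240.8 (II, 2326999 to 2329058) at 1.84. At 60 min T07D1.3, at 1.56, passed with the block (adjusted p = 0.0200). Of 209 detoxification genes 170 were positive at 120 min, with a median of 0.32 (adjusted p = 1.57e-14, but adjusted p = 0.185 with an estimated correlation). Members with the largest statistics, none of which passed over all genes, the list alone or the block, were cyp-13A5 at 2.50, gst-5 at 2.33, ugt-8 at 2.74 and ugt-41 at 1.68.

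Of 26 body wall muscle genes 24 were negative in the TOP-2 strain at 120 min, with a median of -0.43 (adjusted p = 1.03e-05, but adjusted p = 0.951 with an estimated correlation). Values were -1.12 for the titin gene ttn-1, -0.76 for the perlecan gene unc-52 and -0.76 for the vinculin gene deb-1. Of the 26 muscle genes 10 were among the longest 10%, which were lower in this strain by -0.18. The muscle and long-gene changes were not separated. Of 12 heat shock genes 11 were negative, with a median of -1.24 (adjusted p = 4.35e-04, but adjusted p = 0.951 with an estimated correlation). That list changed by -0.196 in replicate 1, which stands apart and was low without auxin, and by -2.30 in replicate 2. Of 16 unfolded protein response genes 14 were negative, with a median of -0.36 (adjusted p = 0.00247, but adjusted p = 0.385 with an estimated correlation), at 0.0129 in replicate 1 and -0.54 in replicate 2. Of 33 replication genes 26 were negative, with a median of -0.16 (adjusted p = 0.00247, but adjusted p = 0.951 with an estimated correlation). No member of these lists passed over all genes tested, with or without the block. The molting cycle (median -0.36) and germline (median -0.18) lists passed with the block alone (adjusted p = 0.00784 and 0.00546, but adjusted p = 0.842 with the block and an estimated correlation). Replicates 1 and 2 had -0.0561 and -0.632 for molting and -0.381 and 0.0911 for the germline.

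The control strain shows what auxin, time and handling did without a tagged protein. After 120 min in CA1200 the neuropeptide receptor gene npr-15 (III, 3683237 to 3685790), named after its value was seen, fell by -1.61 ± 0.22 (adjusted p = 0.0303) and was the only gene called. Its call was lost without any single one of the 4 libraries (no-auxin and 120 min, replicates 1 and 2). With the block 184 genes were higher and 135 lower. The highest of them were the dehydrogenase gene dhs-23 at 5.04, T16G1.6 at 4.99, R09E12.9 at 4.98, cyp-35C1 at 4.70 and mtl-1 at 4.40, which stood at 66.8 ± 72.6 (SD, n = 2) before and 1073 ± 743 after auxin. Among the lowest, R107.5 stood at -5.15, F44E5.5 at -6.95 and F44E5.4 at -6.94, and the near-identical T27E4.3 and T27E4.9, both hsp-16.48, at -5.16. Values of these chaperone copies are uncertain because they share reads. At 30 min 423 genes had an unadjusted p under 0.05 and 0 passed. With the block 13 were higher and 18 lower, among them ugt-8 at 4.42, cyp-35C1 at 4.25, ugt-41 at 3.51, nhr-85 at -1.88, nac-3 at -2.13 and rhy-1 at -2.51. At 60 min 554 genes had an unadjusted p under 0.05, 0 passed, and metr-1 (II, 10926500 to 10931017) at -2.15 passed with the block.

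Of 12 heat shock genes 11 were negative in CA1200 at 120 min, with a median of -3.48 (adjusted p = 2.92e-08, but adjusted p = 0.592 with an estimated correlation), and 7 fell with the block. Of 209 detoxification genes 133 were positive, with a median of 0.21 (adjusted p = 1.8e-08, but adjusted p = 0.389 with an estimated correlation). Of them 7 passed over the list alone, and 25 were higher and 2 lower with the block. Values were 3.39 for cyp-35A2, 3.29 for cyp-13A5, 3.20 for ugt-9 (adjusted p = 0.126) and 2.96 for ugt-41. The unfolded protein response (median -0.51, adjusted p = 1.46e-04, but adjusted p = 0.266 with an estimated correlation) and replication (median -0.21, adjusted p = 9.38e-04, but adjusted p = 0.981 with an estimated correlation) lists were lower. The pathogen response list was higher, with a median of 0.28 (adjusted p = 0.0179, but adjusted p = 0.981 with an estimated correlation). With the block alone, histones (0.48, adjusted p = 3.65e-04), molting (-0.25, 0.00424) and ribosomal proteins (-0.18, 0.0401) passed, with an adjusted p of 0.764, 0.764 and 0.972 with the block and an estimated correlation. Replicates 1 and 2 had 0.191 and 0.884 for histones, -0.756 and 0.00308 for molting, and 0.0869 and -0.394 for ribosomal proteins, so the last 2 changes were each found in only 1 replicate. Without auxin the heat shock list stood at 8.26 and 9.10 in the CA1200 replicates, 10.2 and 9.73 in the TOP-1 strain, and 3.32 and 9.70 in the TOP-2 strain. The low TOP-2 library and the low DPY-27 replicate 1 library, at 3.95, both belong to the 6 libraries that stand apart, and DPY-27 replicate 2 stood at 5.62.

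**Figure D3:**
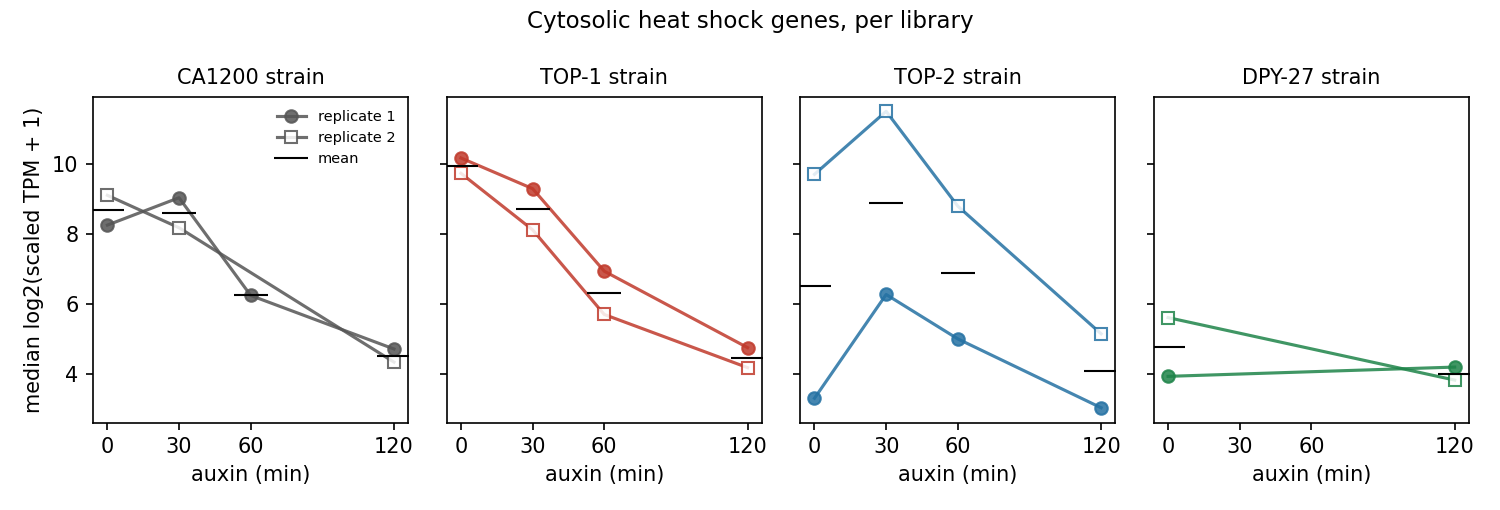
Median log2(scaled TPM + 1) of 12 cytosolic heat shock genes (vertical axis) in each library against minutes of auxin, by strain and replicate. At 120 min the replicates stand at 4.73 and 4.35 in CA1200, 4.77 and 4.20 in the TOP-1 strain, 3.05 and 5.16 in the TOP-2 strain and 4.21 and 3.84 in the DPY-27 strain.

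Degradation of DPY-27 removes the condensin that represses the X in hermaphrodites. After 120 min 7 genes rose and none fell in the DPY-27 strain, and all 7 are named, those outside the rule after their values were seen. C06E4.6 (IV, 7257205 to 7258237) rose by 4.26 ± 0.65, from 0.615 ± 0.272 (SD, n = 2) to 32.1 ± 17.2, and C06E4.3 (IV, 7260873 to 7262017) by 4.11 ± 0.61, from 1.44 ± 0.644 to 40.4 ± 1.12. The cytochrome P450 gene cyp-13A4 (II, 9795788 to 9797681) rose by 3.90 ± 0.50, from 0.383 ± 0.176 to 20.8 ± 9.92. Rises also passed in the lectin gene clec-9 (2.41 ± 0.33), cyp-13A7 (1.99 ± 0.22), the steroid dehydrogenase gene stdh-2 (1.59 ± 0.26) and cyp-33D3 (1.12 ± 0.18). None of the 7 is X-linked, and none of them passed with a pseudocount of 0.1. With the block 18 genes rose, among them T16G1.4 at 2.94, cyp-13A6 at 2.40, ZK742.3 at 2.31, ugt-19 at 2.17 and ugt-20 at 1.65. Without either replicate 1 library 7 genes passed, 2 of them shared, and without either replicate 2 library 0 passed.

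Of 209 detoxification genes 146 were positive in the DPY-27 strain, with a median of 0.21 (adjusted p = 8.4e-11, but adjusted p = 0.429 with an estimated correlation), 3 rose over all genes and 12 over the list alone. Of 33 replication genes 28 were negative, with a median of -0.33 (adjusted p = 6.88e-08, but adjusted p = 0.896 with an estimated correlation), among them the helicase subunit genes mcm-2 at -0.68 and mcm-7 at -0.71. Ribosomal proteins (75 of 76 negative, median -0.32), innate immunity (52 of 77 negative, median -0.16) and stress-induced transcription factors (16 of 19 positive, median 0.24) each had an adjusted p of 0.0369. With an estimated correlation the adjusted p was 0.896 for these 3 lists. The L2/L3 replicate 1 and the mixed-stage replicate 2 had -0.0224 and -0.55 for replication, -0.529 and -0.0864 for ribosomal proteins and -0.329 and -0.0306 for innate immunity. The heat shock list had a median of -0.74 (adjusted p = 0.414). With the block alone, the lists of collagens (-0.26, adjusted p = 0.00453), oxidative phosphorylation (-0.17, 0.00453), muscle (-0.25, 0.00867), neurons (0.15, 0.0133), molting (-0.30, 0.0184) and pathogen response (0.08, 0.0246) passed. With the block and an estimated correlation their adjusted p was 0.841 for oxidative phosphorylation and 0.78 for the others. Molting had 0.101 in replicate 1 and -0.789 in replicate 2, and oxidative phosphorylation -0.218 and 0.00689, so each was lower in only 1 replicate.

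Without auxin, each degron strain was compared with CA1200 to see how the strains differ before treatment. In the TOP-1 strain 0 genes passed in limma (439 at an unadjusted p under 0.05; 448 higher and 290 lower with the block; 138 in the authors' deposited table). All 39 germline genes were positive against CA1200, with a median of 0.61 (adjusted p = 1.57e-08, but adjusted p = 0.769 with an estimated correlation), and 15 were higher with the block. Of 33 replication genes 30 were positive, with a median of 0.53 (adjusted p = 2.17e-12, but adjusted p = 0.769 with an estimated correlation), and 12 were higher with the block. Values were 1.11 for mcm-3, 0.93 for mcm-2 and 0.87 for mcm-4. Higher medians were also found for the pharynx (1.07, adjusted p = 4.84e-04), condensin subunits (0.36, 0.0234), muscle (0.34, 4.5e-05), oocyte and embryo (0.33, 3.16e-04), cohesin (0.28, 0.0234) and DNA damage (0.16, 0.0234). With an estimated correlation the adjusted p was 0.813 for DNA damage and 0.769 for the other 5 lists. Set against the CA1200 mean, replicates 1 and 2 had 0.112 and 1.15 for the germline, 0.0602 and 0.56 for oocyte genes and 0.676 and -0.0235 for muscle. Only with the block, heat shock (0.84, adjusted p = 0.0224), detoxification (-0.12, 0.0495) and starvation (-0.26, 0.0495) passed, with an adjusted p of 0.728, 0.728 and 0.683 with the block and an estimated correlation. The X minus autosome value was -0.01 (adjusted p = 0.725) and turned to 0.00259 without CA1200 replicate 1 and to 0.0566 without TOP-1 replicate 2, and was -0.0785 without TOP-1 replicate 1.

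In the TOP-2 strain without auxin 0 genes passed against CA1200 (897 at an unadjusted p under 0.05; 1712 higher and 1732 lower with the block; 98 in the authors' deposited table). Its replicate 1 is among the 6 libraries that stand apart. The pathogen response list was higher, with 34 of 41 genes positive and a median of 0.77 (adjusted p = 1.32e-09, but adjusted p = 0.907 with an estimated correlation, as for all 8 lists called here). Higher too were the germline (0.72, 5.39e-06), pharynx (1.78, 0.00314), DNA damage (0.40, 0.00442), oocyte (0.36, 0.0114) and muscle (0.34, 0.0225) lists. Ribosomal proteins (-0.89, adjusted p = 5.28e-06) and heat shock genes (-1.41, 0.00442) were lower, again with an adjusted p of 0.907 with an estimated correlation. Most of these differences came from replicate 1. Set against the CA1200 mean, replicates 1 and 2 had 1.02 and 0.331 for the pathogen response, 1.2 and 0.0895 for the germline, 3.33 and 0.203 for the pharynx and 0.804 and -0.0584 for DNA damage. They had 0.692 and 0.0325 for oocyte genes, -0.0391 and 0.713 for muscle, -2.2 and 0.42 for ribosomal proteins and -3.69 and 0.718 for heat shock. Passing only with the block were hypodermis (-0.37, adjusted p = 0.0299), replication (0.19, 0.0457) and oxidative phosphorylation (-0.10, 0.0467), with an adjusted p of 0.62, 0.883 and 0.883 with the block and an estimated correlation. The last 2 had 0.584 and -0.062, and -0.847 and 0.64, in the replicates. The X minus autosome value was -0.03 (-0.0615 and 0.0124 in the replicates, adjusted p = 0.584), 0 without TOP-2 replicate 1 and -0.0537 without TOP-2 replicate 2.

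In the DPY-27 strain without auxin 56 genes were higher, 21 of them X-linked, and 12 lower than in CA1200. The thaumatin gene thn-2 (IV, 12383143 to 12383983) was higher by 4.90 ± 0.68, at 33.3 ± 31.3 (SD, n = 2) against 0.692 ± 0.212. The insulin-like gene ins-20 (II, 6010817 to 6011295) was higher by 4.80 ± 0.74, C45B2.1 (X) by 4.59 ± 0.95, suex-1 by 4.52 ± 0.53 and ZK673.1 by 4.38 ± 0.84. Lower genes were C01B10.7 (-3.77 ± 0.64), nac-3 (-2.47 ± 0.49), hot-4 (-1.99 ± 0.36), T26G10.5 (-1.95 ± 0.39) and C56G2.9 (-1.90 ± 0.34). X-linked genes were higher relative to autosomes by 0.43 (0.405 and 0.505 in the replicates, adjusted p = 3.73e-07). These differences rest on the level of replicate 1, which stands apart, since the fitted mixed-stage term takes up that of replicate 2. With the block 3431 genes were higher and 2990 lower, and with TPM as deposited 34 and 2. The count of 68 became 2 without CA1200 replicate 1, 5 without CA1200 replicate 2, 0 without DPY-27 replicate 1 and 26 without DPY-27 replicate 2. The authors' deposited table calls 683 genes higher and 215 lower, and 215 of its higher genes are X-linked. At 120 min 29 genes were higher, 9 of them X-linked, and 3 lower, and the X minus autosome value was 0.57.

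The list differences of the DPY-27 strain without auxin rest in the same way on replicate 1, which stands apart, and several were absent from the mixed-stage replicate 2. Set against the CA1200 mean, replicates 1 and 2 had 1.18 and -0.002 for the germline, 0.71 and 0.02 for oocyte genes, -1.27 and 0.16 for ribosomal proteins, and -0.69 and 0.18 for oxidative phosphorylation. They had 3.33 and 1.3 for the pharynx, 0.94 and 0.13 for the pathogen response, 0.35 and 0.04 for detoxification, 0.62 and 0.28 for DNA damage, 0.50 and 0.64 for replication and -3.66 and -1.92 for heat shock. In the fit, the pharynx list had a median of 3.38 against CA1200 (adjusted p = 3.37e-06, but adjusted p = 0.838 with an estimated correlation, as for all 10 lists called here; 8 genes over the list alone), with pqn-75 at 1.92 (adjusted p = 0.045). Higher lists were the germline (1.27, adjusted p = 1.89e-05), pathogen response (0.91, 1.89e-05, 4 genes over the list alone), oocyte (0.74, 0.00203), DNA damage (0.71, 6.98e-04), replication (0.58, 0.00193) and detoxification (0.34, 0.00654, 16 genes over the list alone). In the last, cyp-34A7 was higher by 2.92 and ugt-18 by 3.77. Heat shock (-3.18, adjusted p = 1.44e-04), ribosomal proteins (-1.36, 3.37e-06) and oxidative phosphorylation (-0.67, 0.00156) were lower, again with an adjusted p of 0.838 with an estimated correlation. Only with the block did histones (-0.55, adjusted p = 0.0174), collagens (-0.44, 0.0202), condensin (0.69, 0.0276) and cohesin (0.49, 0.0276) pass, with an adjusted p of 0.672 with the block and an estimated correlation. The lysozyme gene lys-7 was higher by 3.79 and col-181 by 1.41 (both with an adjusted p of 0.045).

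Strains were also compared at later times. In the TOP-1 strain 0 genes passed at 30 and 60 min (351 and 481 at an unadjusted p under 0.05; 44 and 16 in the authors' deposited tables), and with the block 186 were higher and 199 lower at 30 min and 60 and 123 at 60 min. At 120 min 12 were higher and 23 lower, 16 of the latter among the longest. T20D4.12 (V, 3397061 to 3397786) was higher by 3.27 ± 0.38, at 56.9 ± 13 (SD, n = 2) against 5.01 ± 1.53, the tubulin gene tbb-6 by 2.29 ± 0.31 and fipr-21 (X) by 2.14 ± 0.36. Lower were Y48E1B.3 (-2.21 ± 0.31), Y64G10A.7 (-1.94 ± 0.27) and Y50D7A.3 (-1.91 ± 0.29). The block gave 945 and 941 at 120 min, and the authors' deposited table calls 72 higher and 88 lower. The count of 35 became 3 without CA1200 120 min replicate 1, 1 without CA1200 replicate 2, 3 without TOP-1 replicate 1 and 8 without TOP-1 replicate 2.

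In the TOP-2 strain against CA1200 0 genes passed at 30, 60 and 120 min, with 538, 239 and 218 at an unadjusted p under 0.05. The authors' deposited tables call 103, 0 and 76. With the block 1228 were higher and 781 lower at 30 min, 210 and 186 at 60 min and 877 and 625 at 120 min. In the DPY-27 strain at 120 min ins-20 was higher by 5.07 ± 0.74, thn-2 by 3.74 ± 0.68 and suex-1 by 3.66 ± 0.53, and clec-1 (-3.32 ± 0.63), T10G3.8 (-1.99 ± 0.35) and anmt-2 (-1.34 ± 0.25) were lower. The block gave 3235 higher and 2688 lower there, and the authors' deposited table calls 371 higher, 144 of them X-linked, and 179 lower. The count of 32 became 10 without CA1200 replicate 1, 15 without CA1200 replicate 2, 7 without DPY-27 replicate 1 and 16 without DPY-27 replicate 2.

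The last question was whether the 120 min change differs between strains. The authors' deposited tables hold no such comparison, nor any within CA1200 or the DPY-27 strain. No gene passed for the TOP-1 strain minus CA1200 in limma (462 at an unadjusted p under 0.05), and 79 were higher and 171 lower with the block. Those were headed by T20D4.12 at 2.67, C04A11.5 (X) at 2.41, grd-3 at 2.12, F54B11.9 (X) at 2.097 and F11E6.11 at 2.05, and by dpy-1 (III, 2034966 to 2047112) at -3.26, F33D4.6 at -2.93, the patched-related gene ptr-18 at -2.93, the cadherin gene cdh-12 at -2.81 and the molting gene mlt-11 at -2.66. No list passed. With the block alone, ribosomal proteins (0.38, adjusted p = 7.37e-04), molting (-0.52, 0.00450) and heat shock (-1.1, 0.0325) did, with an adjusted p of 0.941 with the block and an estimated correlation. For the TOP-2 strain minus CA1200 no gene passed with or without the block (108 at an unadjusted p under 0.05). Histones were lower (24 of 32 negative, median -0.61, adjusted p = 0.0498), muscle lower (21 of 26, -0.27, 0.0271) and heat shock higher (12 of 12, 1.45, 0.0293), with an adjusted p of 0.971 with an estimated correlation. Of the 26 muscle genes 10 were among the longest 10%, so the muscle and long-gene differences overlap. The heat shock list changed by -0.196 and -2.30 in TOP-2 replicates 1 and 2 and by -1.98 and -4.26 in CA1200. TOP-2 replicate 1 was already low without auxin, at 3.32 on the log2 scale. Under the block alone, ribosomal proteins (0.27, adjusted p = 6e-04), pathogen response (-0.27, 0.0123), germline (-0.17, 0.0173) and collagens (-0.13, 0.0460) passed, with an adjusted p of 0.975 with the block and an estimated correlation.

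For the DPY-27 strain minus CA1200 no gene passed (132 at an unadjusted p under 0.05), and ugt-19 at 2.53 and npr-15 at 1.63, chosen after their values were seen, passed with the block (both with an adjusted p of 0.0443). The 120 min change was higher for heat shock (12 of 12, median 2.64, adjusted p = 8.82e-07). It was lower for innate immunity (59 of 77, -0.45, 5.82e-04), collagens (99 of 131, -0.32, 0.0068) and intestine (19 of 26, -0.34, 0.0278). Each of these lists had an adjusted p of 0.935 with an estimated correlation. The change was also higher for the unfolded protein response (14 of 16, median 0.35, adjusted p = 0.00121, but adjusted p = 0.51 with an estimated correlation). The heat shock list was already low without auxin in the DPY-27 strain, at 3.95 and 5.62 on the log2 scale in replicates 1 and 2. CA1200 then stood at 8.26 and 9.10. At 120 min the levels were 4.21 and 3.84 in the DPY-27 strain and 4.73 and 4.35 in CA1200. The difference is thus not a higher level after auxin. Under the block alone, histones (-0.33, adjusted p = 0.00103) and neurons (0.24, 0.0154) passed, with an adjusted p of 0.754 with the block and an estimated correlation. Between the TOP-1 and TOP-2 strains no gene passed (453 at an unadjusted p under 0.05), and with the block 77 changes were higher and 160 lower in the TOP-1 strain. They were headed by F46C5.1 at 4.60, C50F7.5 at 3.23, C17B7.4 at 2.88, M02D8.6 at 2.80 and K01A12.4 at 2.70, and by hsp-16.2 at -4.92, rhy-1 at -3.17, mlt-11 at -2.75, cdh-12 at -2.65 and Y60A3A.19 at -2.18. Heat shock (12 of 12 negative, median -2.47, adjusted p = 1.77e-04) and the unfolded protein response (12 of 16 negative, median -0.44, adjusted p = 0.0467, or 0.0503 with the block) were lower, with an adjusted p of 0.983 with an estimated correlation. The heat shock list changed by -4.81 and -4.54 in TOP-1 replicates 1 and 2 and by -0.196 and -2.30 in those of the TOP-2 strain. TOP-2 replicate 1 was already low without auxin, at 3.32 on the log2 scale. Molting passed with the block alone (median -0.69, adjusted p = 2.82e-04, but adjusted p = 0.886 with the block and an estimated correlation).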

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

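Each result here is a difference between strains in the 120 min change that passed its test with the preset correlation between genes. The tests for a change common to all strains, the correlations with the DPY-27 strain's own 120 min change and all tests of causes for the heat shock genes were chosen after the results were seen. The other tests of causes were written down earlier, and the gene lists were fixed before the data were examined.

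X-linked genes rose more than in CA1200 by 0.191 in the TOP-1 strain, 0.218 in the TOP-2 strain and 0.121 in the DPY-27 strain. Gene length or level could have produced the rise within the degron strains. Among genes matched on both, the lowest of the 6 replicate values of that rise was still 0.131. The difference from CA1200 was not matched in this way. A change with time, handling or auxin common to all strains is also not favoured, since the lowest replicate of the degron strains exceeded the highest CA1200 replicate by 0.0741. The biological explanation tested was a loss of condensin DC function that ranks X-linked genes as the DPY-27 strain differs from CA1200 without auxin. That rank correlation was lower on the X than on autosomes, by -0.152 in the TOP-1 strain (0.107 against 0.259). In the TOP-2 strain the difference was -0.0574 (-0.0093 against 0.0481). The excess on the X predicted beforehand was thus absent in both strains, which counts against this explanation by the rule written down earlier. However, that test rests on a DPY-27 library that stands apart. Pearson correlations with the DPY-27 strain's own 120 min change were chosen after the results were seen. They were 0.402 on the X against 0.365 on autosomes in the TOP-1 strain and 0.352 against 0.350 in the TOP-2 strain. With that limit, the explanation is left open.

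The longest 10% of genes fell further than in CA1200 by -0.476 in the TOP-1 strain and -0.139 in the TOP-2 strain (adjusted p = 0.0723 and 0.506 with an estimated correlation). A bias with expression level could lie behind the change within the TOP-1 strain, but with genes matched on level its weaker replicate still had -0.399. The difference from CA1200 was not matched in this way. The phase of the molting cycle cannot be told apart from the degradation of TOP-1. Among genes alike in the TOP-1 replicates the weaker replicate had -0.423, but a shift shared by both passes that selection. The molting list changed by -1.03 and -0.848 in the TOP-1 replicates, but 8 of its 36 members are among the longest 10%. It is therefore not a separate measure of phase. Replicates with molting changes of -0.756 (CA1200), -0.789 (DPY-27 strain) and -0.632 (TOP-2 strain) had long-gene values of only -0.0934, -0.00296 and -0.121. A common effect of time, handling or auxin is not favoured at 120 min, where the TOP-1 replicate that fell least lay -0.370 below the CA1200 replicate that fell most, but at 30 min that gap was -0.0257 and the explanations cannot be told apart, and at 60 min, with 1 CA1200 library and no test, the values were -0.33 in CA1200 and -0.47 in the TOP-1 strain, which leaves it open. The degradation of topoisomerase I is the biological explanation in the design, and it stays open.

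The heat shock list moved less than in CA1200, by 1.45 in the TOP-2 strain and 2.64 in the DPY-27 strain, and differed by -2.47 between the TOP-1 and TOP-2 strains (adjusted p = 0.971, 0.935 and 0.983 with an estimated correlation). Degradation of TOP-1 is not a likely source of the fall itself, since the list median of the CA1200 replicate that fell least changed by -1.98. For the 7 members without a near-identical copy, the weakest of the 4 replicate medians in CA1200 and the TOP-1 strain was -1.46. That speaks against shared reads as the only source. The 6 libraries that stand apart could account for the low level without auxin in TOP-2 replicate 1, and there the explanations cannot be told apart: both such no-auxin libraries were low, the higher of them at -4.31 from the lower CA1200 library. In the DPY-27 strain the mixed-stage library, which is not among the 6, was low too, at -2.63 from that CA1200 library. No other biological explanation was tested.

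In the TOP-2 strain minus CA1200, histones had a median of -0.608 and body wall muscle genes -0.267 (both with an adjusted p of 0.971 with an estimated correlation). Of the 26 muscle genes 10 were among the longest 10%, so the muscle and long-gene differences overlap. In the DPY-27 strain minus CA1200, the medians were 0.352 for the unfolded protein response, -0.452 for innate immunity, -0.322 for cuticle collagens and -0.342 for the intestine (adjusted p = 0.51 for the first and 0.935 for the others with an estimated correlation). In CA1200 itself the 120 min changes of replicates 1 and 2 were 0.191 and 0.884 for histones, 0.416 and -0.0741 for innate immunity and 0.582 and -0.163 for the intestine. The unfolded protein response differed by -0.441 between the TOP-1 and TOP-2 strains (adjusted p = 0.983 with an estimated correlation).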

How the results depend on the processing

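The alternatives were written down before any result was seen, with exceptions. The replicate block was not planned for the gene lists. Leaving out the 6 libraries that stand apart was chosen after seeing the data. The rise of X-linked genes at 120 min in the TOP-1, TOP-2 and DPY-27 strains kept its direction and its call under every alternative, and so did the X-linked excess of the DPY-27 strain without auxin. Counts of genes past the threshold depended strongly on how the spread between libraries was estimated. Within the TOP-2 strain and CA1200, the main fit gave fewer genes at an unadjusted p under 0.05 than expected without any change. A low count there does not show that few genes changed. Of 520 values of named genes under the alternatives, 221 kept their call, 299 no longer passed and 0 turned direction. Of 240 values for X-linked and long genes, 215 were the same, 12 no longer passed, 2 newly passed and 11 turned direction. In simulated data for the TOP-1 strain at 120 min, the main fit recovered 2.39% of genes changed by 1 on the log2 scale and the fit with the replicate block 52.4%, from the same libraries. The simulated data were drawn from the fit with the block, so its advantage there was built in. What depth, 5.74 to 21.4 M fragments, limits was not tested. Where no cause is named below, the cause was not tested.

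With an estimated correlation between genes, 0 of 297 list tests passed, against 56, and the long-gene differences no longer passed: -0.498 and -0.179 within the TOP-1 and TOP-2 strains, and -0.476 and -0.139 against CA1200. The cause was not tested.

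With the replicate block, which removes variation between replicates of a strain, counts within strains were 698, 2090 and 3280 at 30, 60 and 120 min in the TOP-1 strain against 1, 74 and 277. They were 3 and 1 at 30 and 60 min in the TOP-2 strain against 0 and 0, 31, 1 and 319 in CA1200 against 0, 0 and 1, and 18 in the DPY-27 strain against 7. Between strains the block gave 738, 385, 183 and 1886 genes for the TOP-1 strain from 0 to 120 min against 0, 0, 0 and 35, and 3444, 2009, 396 and 1502 for the TOP-2 strain against 0 at each time. For the DPY-27 strain it gave 6421 and 5923 at 0 and 120 min against 68 and 32. For differences between changes it gave 250 for the TOP-1 strain and 2 for the DPY-27 strain minus CA1200, and 237 between the TOP-1 and TOP-2 strains, against 0 each. Under the block 88 lists passed, against 56, and with the block and an estimated correlation 0 passed. Beyond these and the calls given in the report, the block changed no other call of a list as a group or of X-linked or long genes. Calls of members over a list alone are not all given here.

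With a pseudocount of 0.1, 1 gene passed at each time in the TOP-2 strain against 0, 0 in CA1200 at 120 min against 1, 0 in the DPY-27 strain against 7, and 2 and 0 between the DPY-27 strain and CA1200 at 0 and 120 min against 68 and 32. The cause was not tested.

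With no filter, 18 genes passed in the TOP-1 strain at 60 min against 74, 1 and 2 in the TOP-2 strain at 30 and 60 min against 0, 9 and 3 in CA1200 at 60 and 120 min against 0 and 1, and 18 in the DPY-27 strain against 7. Between strains the counts were 7 and 61 for the TOP-1 strain at 60 and 120 min against 0 and 35, 4, 8 and 3 for the TOP-2 strain at 30, 60 and 120 min against 0, and 204 and 190 for the DPY-27 strain against 68 and 32. For the change in the TOP-1 and in the DPY-27 strain minus CA1200, 1 gene passed each, against 0. The long-gene value in the DPY-27 strain turned from 0.00947 to -0.00384. More genes enter the test here, but the cause was not tested.

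With TPM as deposited, 0, 0 and 9 genes passed in the TOP-1 strain against 1, 74 and 277, 1 in the TOP-2 strain at 120 min against 0, and 0 in CA1200 at 120 min against 1. Between strains 0 passed for the TOP-1 strain at 120 min against 35, 1 for the TOP-2 strain at 120 min against 0, and 36 for the DPY-27 strain without auxin against 68. For the TOP-2 change minus CA1200 1 gene passed against 0. The X minus autosome value of the TOP-2 strain at 30 min turned from -0.00433 to 0.0167. The cause was not tested.

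With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, 0 genes passed in the TOP-1 strain at any time, in CA1200 at 120 min, in the DPY-27 strain at 120 min and for the TOP-1 strain against CA1200 at 120 min. Against that, 932 and 1388 passed for the DPY-27 strain against CA1200 at 0 and 120 min, and the cause was not tested.

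Without the 6 libraries that stand apart, chosen after seeing the data, 8, 217 and 631 genes passed in the TOP-1 strain, and 262 of the 277 at 120 min were among them. Counts were 4, 6 and 7 in the TOP-2 strain, 6, 8 and 45 in CA1200 and 14 in the DPY-27 strain, whose long-gene value turned to -0.00296. Between strains they were 2 and 69 for the TOP-1 strain at 60 and 120 min, 4, 15 and 2 for the TOP-2 strain at 0, 30 and 60 min, and 24 and 81 for the DPY-27 strain, whose remaining libraries are mixed-stage. For the changes, 2 genes passed for the TOP-2 strain and 4 for the DPY-27 strain minus CA1200, and 3 between the TOP-1 and TOP-2 strains. The cause was not tested.

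With each library left out in turn, a lone library is assumed to vary like the other groups, and fewer libraries enter each test. Counts ran from 0 to 0, 0 to 3 and 16 to 109 in the TOP-1 strain at 30, 60 and 120 min, 0 to 1 in the TOP-2 strain at 120 min, 0 to 1 in CA1200 at 30 and at 120 min, and 0 to 7 in the DPY-27 strain. Between strains they ran from 0 to 1 for the TOP-1 strain at 30 and at 60 min, 1 to 8 at 120 min, 0 to 1 for the TOP-2 strain at 30 and at 120 min, and 0 to 26 and 7 to 16 for the DPY-27 strain at 0 and 120 min. For the changes in the TOP-1 strain and the TOP-2 strain minus CA1200, and between those 2 strains, they ran from 0 to 1. X minus autosome values ran from 0.0399 to 0.189 in the TOP-1 strain at 30 min, -0.0358 to 0.0260 and 0.0901 to 0.198 in the TOP-2 strain at 30 and 60 min, -0.0785 to 0.0566 for the TOP-1 strain against CA1200 without auxin, and 0.0940 to 0.142 for the DPY-27 change minus CA1200. Long-gene values ran from -0.206 to 0.136 in CA1200, -0.00296 to 0.0102 in the DPY-27 strain and -0.314 to 0.030 for the TOP-2 change minus CA1200. The cause was not tested.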

Other observations

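X-linked genes were also compared with autosomal genes by position on the X and by span. In 10 equal parts of the X chromosome, the X minus autosome value at 120 min ran from 0.0329 in the first part to 0.363 midway along it in the TOP-1 strain, from 0.190 to 0.30 in the TOP-2 strain and from 0.0903 to 0.193 in the DPY-27 strain, while CA1200 had 0.000683 to 0.0602. In 5 classes by span, from shortest to longest, it was 0.154, 0.180, 0.154, 0.260 and 0.473 in the TOP-1 strain and 0.209, 0.198, 0.201, 0.283 and 0.322 in the TOP-2 strain. The DPY-27 strain had 0.0818, 0.103, 0.141, 0.186 and 0.188, and CA1200 had 0.0502, 0.00601, -0.0258, 0.0401 and 0.0400. The first part in the TOP-1 strain, with replicates at -0.00247 and 0.000921, lies within the range of CA1200. These are values without a test.

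The course of the heat shock genes at 30 and 60 min differed between measures. The list median on the log2 scale was 9.04 and 8.18 at 30 min and 6.25 at 60 min in CA1200, 9.29 and 8.12 and then 6.94 and 5.71 in the TOP-1 strain, and 6.28 and 11.5 and then 5.01 and 8.79 in the TOP-2 strain. The median of the changes of single genes from no auxin to 60 min was -0.0497 in CA1200, -1.77 and -1.89 in the TOP-1 strain and 0.566 and 0.33 in the TOP-2 strain. In CA1200 replicate 1, hsp-70 stood at 50.03 without auxin and 68.8 at 60 min, and hsp-16.2 at 377 and 749. The 120 min changes of all genes, compared across genes between strains that share no libraries, had correlations of 0.615 between the TOP-1 strain and CA1200, 0.547 between the TOP-1 and TOP-2 strains, 0.519 between the TOP-2 strain and CA1200, 0.420 between CA1200 and the DPY-27 strain, 0.379 between the TOP-1 and DPY-27 strains and 0.367 between the TOP-2 and DPY-27 strains. Genes are not independent replicates, so no p is given.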
